A study of Homo sapiens with 24 samples.

How the data were processed

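The data are 24 Illumina expression arrays of HCT116 cells, 3 for each of 8 groups that cross siMock or siACL with butyrate at 0, 0.5, 2 or 5 mM for 3 days. Per the labels, total RNA was prepared with Trizol, checked on a Bioanalyzer and turned into biotinylated cRNA with an Ambion MessageAmp kit for Illumina arrays. The replicates are called biological in the labels, and culture dates, slides and batches are not given in the sources used here.

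The score values were used as deposited by the authors, who give no description of how they made them. The deposited table holds 20747 entries on a scale from -3.90 to 3.90. On every array the values follow the normal quantiles of the ranks, with a largest gap of 0.00074, so each value is a normal score of a rank within its array. The scale is neither log2 nor a signal, so a difference of scores has no fold change, and a change shared by all genes would not be seen. Background correction, probe selection and software are not given in the sources used here. A second deposited table holds scanner values in 48 columns, 24 of signal and 24 of detection p, whose names are tied to no sample in the labels. These 48 columns were not used, and signal over background is therefore unknown. Only the gene annotation of that table was used. The design written before the data were examined expected log2 signals with background correction, quantile normalization and a detection filter, and its tests were applied to the scores in place of log2 values. No filter was applied.

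Of the 20747 entries, 20729 were found in the annotation of 34592 entries and 18 were kept without it. The 18172 with a gene symbol, each symbol once, were tested and 2575 without one were left out. Symbols were compared with RefSeq names of human genes: 12258 were matched by accession and 1994 have a changed symbol, while 243 current symbols are measured by more than 1 entry. At most 0.222% of the genes had identical values in any 2 arrays, so no array repeats another.

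Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 arrays, no block and moderated t-tests (residual degrees of freedom 16, prior degrees of freedom 1.05). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 13 comparisons were each dose against untreated in siMock and in siACL, siACL against siMock at each dose, and the siACL change minus the siMock change at each dose. The median residual SD of a gene was 0.416, 0.189, 0.047 and 0.033 in the 4 classes of genes from lowest to highest mean score. Scores of weakly expressed genes are therefore less precise. In simulated data with 200 changed genes of 18172, differences of 0.25, 0.5 and 1 were found for 50.7%, 59.7% and 69.7% of genes in siMock at 0.5 mM. They were found for 47.8%, 58.2% and 75.8% in siACL against siMock without butyrate and for 31.3%, 50.7% and 54.5% in the interaction at 5 mM. Of the calls there, 4%, 5.5% and 6.2% were unchanged genes. In the real data 22.1% of genes were called in siMock at 0.5 mM and 50.8% at 5 mM. With so few changed genes the simulation does not test false calls from displaced ranks. Its error and recovery rates need not hold for these data.

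The comparisons, tests, thresholds, 32 gene lists and the rule for naming genes were fixed before the data were examined. The rule names ACLY everywhere. For siMock doses, siACL against siMock without butyrate and the interactions it names the 8 largest rises and 8 largest falls, and for siACL doses 5 and 5. These are taken among called genes with an approved-style symbol whose arrays in the groups compared do not overlap, without the overlap condition for interactions. It also names up to 4 of the largest called members of each list, or all of them where 5 or fewer are called. Second measurements of a named gene (DSCR1L1, C20ORF45, NUF2) were added after their values were seen. Some genes that the rule names are not reported here. Lists were tested with camera, with a preset correlation of 0.01 between genes, adjusted over the 32 lists of a comparison, and repeated with an estimated correlation. Changes in the 2 arms were compared by Pearson correlation and slope across genes, and changes at doses that share untreated arrays were set beside 100 simulated sets of unchanged groups. Principal components were computed from the centred scores of the genes tested.

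Alternatives tried were fits on only the arrays compared, array weights, a trend and robust variance prior, the replicate number as a block, a stricter threshold and leaving out each array in turn. Chosen after seeing the data were all entries with and without a symbol, genes with a mean score above 0, percentile ranks, a minimum difference of 0.25 and 0.5 mM as the reference. Other splits of the arrays were refitted, all 10 for 3 arrays against 3 and 100 for an interaction.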

Results

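Transcript levels were measured on 24 Illumina expression arrays of HCT116, a human colorectal carcinoma cell line. Control cells transfected with siMock and cells depleted of ATP citrate lyase with siACL were each left untreated or given butyrate at 0.5, 2 or 5 mM for 3 days. Butyrate is a short-chain fatty acid made by gut bacteria that colonocytes burn as fuel and that inhibits histone deacetylases, and ATP citrate lyase turns citrate into cytosolic acetyl-CoA. Each of the 8 groups held 3 arrays, which the labels call biological replicates. The design asks how the response to butyrate changes with its dose and whether it differs when ATP citrate lyase is reduced.

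Values are normal scores, that is, each gene's rank within its array placed on a standard normal curve. A score of 0 is the middle of the array and no fold change can be given. Every array holds nearly the same set of scores, so rises of some genes must be offset by falls of others. The balance of higher and lower counts therefore follows in part from the scale. A fall can also be a rank displaced by rises of other genes. Differences between groups are given as the difference of mean scores ± its standard error from limma, with 3 arrays per group, and group levels as mean ± SD (n = 3). Symbols are those of the array annotation, with the current symbol in parentheses where it differs. A gene is said to rise or fall where its Benjamini-Hochberg adjusted p was under 0.05 over the 18172 genes tested. Genes named by size had the largest differences among called genes whose arrays in both groups did not overlap, which chance alone gives for 10% of genes. Of a gene list's measured members, those given neither as higher nor as lower did not pass. List p-values are from camera with a preset correlation between genes, and 110 of its 138 list calls held with an estimated correlation. Adjusted p-values of calls that held can be far larger with an estimated correlation. For mitosis genes in siACL against siMock at 5 mM it was 3.17e-10 in place of 7.77e-50.

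Arrays of one group correlated with each other at r = 0.928 to 0.955 over genes. The first principal component held 30.3% of the variance and ordered the groups by dose in both arms. Its mean score went from -24.8 in untreated siMock through -6.7 and 16.2 to 37.8 at 5 mM. In siACL it went from -27.8 in untreated arrays through -19.5 and -1.9 to 26.7. On the second component, with 6.9% of the variance, untreated siMock lay at 19.1 and untreated siACL at 3.6.

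**Figure D1:**
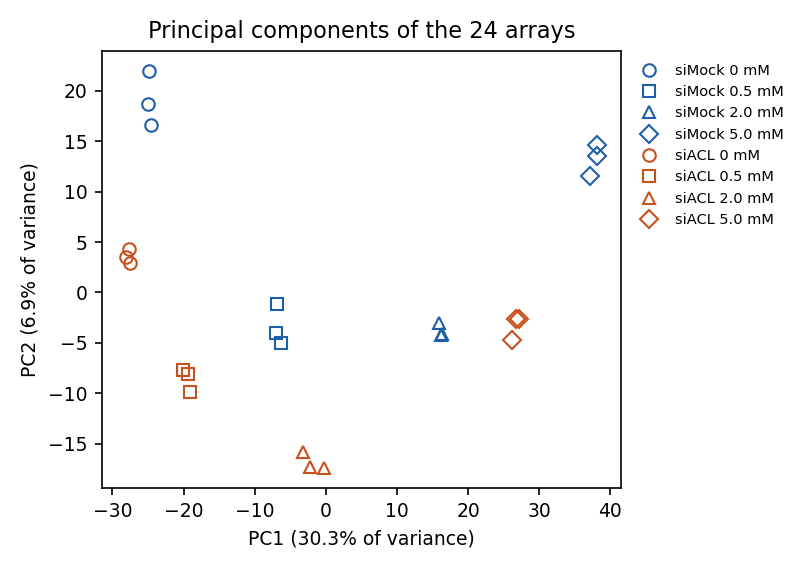
Each symbol is 1 of the 24 arrays, placed by its scores on the first (30.3% of variance) and second (6.9%) principal components of all genes tested; colours mark siMock and siACL and shapes the butyrate dose in mM. At 0.5, 2 and 5 mM the siACL arrays lie to the left of the siMock arrays of the same dose. Without butyrate they do too (means -27.8 in siACL and -24.8 in siMock).

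ACLY, the gene of ATP citrate lyase and the target of the knockdown, was lower in siACL than in siMock at each dose. Its score was 1.52 ± 0.02 in untreated siMock, the 93.6 percentile of the array, and 1.19 ± 0.02 in untreated siACL, the 88.2 percentile. The difference was -0.34 ± 0.02 without butyrate (adjusted p = 6.3e-08), -0.41 ± 0.02 at 0.5 mM, -0.42 ± 0.02 at 2 mM and -0.63 ± 0.02 at 5 mM (adjusted p = 1.4e-11). In siMock, ACLY fell with butyrate at 2 mM (-0.15 ± 0.02) and 5 mM (-0.21 ± 0.02), while the difference at 0.5 mM was -0.01 ± 0.02 (adjusted p = 0.89). In siACL it fell at 0.5 mM (-0.08 ± 0.02, adjusted p = 0.047), 2 mM (-0.23 ± 0.02) and 5 mM (-0.50 ± 0.02). On the score scale the fall at 5 mM was larger in siACL than in siMock by an interaction of -0.29 ± 0.03 (adjusted p = 1.3e-05). The arms started from different scores, so this need not hold for transcript amounts. At 5 mM the siACL score was 0.68 ± 0.02, the 75.3 percentile.

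**Figure D2:**
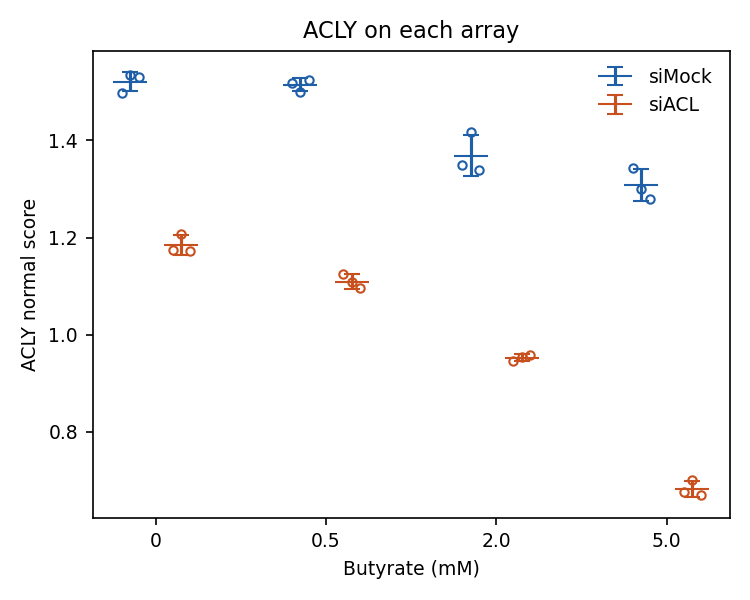
Points are the ACLY normal scores of the 24 arrays (vertical axis, score) at each butyrate dose (horizontal axis, mM, evenly spaced), with horizontal bars for the mean of 3 arrays and whiskers for the SD. Each siACL array lies below the siMock arrays of its dose, with means of 1.52 in siMock and 1.19 in siACL without butyrate and 1.31 and 0.68 at 5 mM.

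The first question was what butyrate did in control cells. At 0.5 mM, 4022 of 18172 genes changed in siMock, with 2180 higher and 1842 lower. At 2 mM 6894 changed (3395 higher and 3499 lower), and at 5 mM 9237 (4655 higher and 4582 lower). At 5 mM all 30 measured mitosis genes fell, lists of metallothioneins, histone genes and neuronal genes rose, and lists of DNA replication and ribosome biogenesis genes fell at each dose. The median size of the called differences went from 0.171 at 0.5 mM to 0.219 and 0.295 at 2 and 5 mM.

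Among the genes with the largest rises in siMock at 5 mM were ZNF264, a zinc finger gene (4.00 ± 0.17), PAGE4 of the GAGE and PAGE family (3.63 ± 0.22), and GAST, the gene of the hormone gastrin (3.61 ± 0.22). CNTNAP2, a neurexin-related cell adhesion gene, rose by 3.52 ± 0.12, CST1, a cystatin, by 3.51 ± 0.14, and ODZ3 (TENM3), a teneurin, by 3.50 ± 0.18. GRP, which encodes gastrin-releasing peptide, rose by 3.47 ± 0.16 and FAM174B by 3.42 ± 0.19. At the lower doses ZNF264 and CNTNAP2 led, with 3.53 and 2.80 at 0.5 mM and 3.67 and 3.25 at 2 mM. Scores of ZNF264 were low in untreated siMock alone, where every array lay at least 3.11 below every array of the other groups. Other large rises at 0.5 mM were those of AFAP1L2, an actin-associated adaptor (2.70 ± 0.06), PAGE4 (2.52 ± 0.22), ARHGDIB (2.35 ± 0.10), RCAN2, a calcineurin regulator (2.27 ± 0.09), OLFM1 (2.22 ± 0.09) and EFHD1 (2.15 ± 0.15). For RCAN2 the arrays hold a second measurement under the older name DSCR1L1, whose difference was -0.589 and did not pass the test. ARHGDIB was also low in untreated siMock alone, by at least 1.31. At 2 mM, CST1 (3.22 ± 0.14), PAGE4 (3.23 ± 0.22), GRP (3.18 ± 0.16), the MHC class II gene HLA-DPA1 (3.17 ± 0.12), the Wnt antagonist gene DKK4 (3.14 ± 0.27) and LRRC26 (2.93 ± 0.61) were also among the largest rises.

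Among the largest falls in siMock, ZBED2, a zinc finger gene, had differences of -4.03 ± 0.28 at 5 mM and -3.45 ± 0.28 at 2 mM. GCNT3, a glycosyltransferase that builds mucin-type glycans, fell at each dose, with -2.21, -2.38 and -2.80. The other large falls at 5 mM were in SNCG, the gene of gamma-synuclein (-3.25 ± 0.20), ARMC4 (-2.91 ± 0.20), the adhesion receptor gene GPR110, now ADGRF1 (-2.53 ± 0.12), and CDCA1, an older name of the kinetochore gene NUF2 (-2.50 ± 0.31). SLC22A18AS (-2.50 ± 0.18) and the keratin gene KRT7 (-2.49 ± 0.24) fell too. The measurement listed as NUF2 fell by 0.781. At 2 mM ARMC4 (-2.61 ± 0.20), GPR110 (-2.33 ± 0.12) and SLC22A18AS (-2.21 ± 0.18) were already lower, as were SLC16A14 (-2.04 ± 0.19), SLC25A21 (-2.00 ± 0.34) and CTRL, a chymotrypsin-like protease gene (-1.93 ± 0.25). At 0.5 mM NAV3, a neuron navigator gene, had a difference of -2.06 ± 0.40 (adjusted p = 0.001). Other differences there were SLMO2 (PRELID3B) -1.5 ± 0.39, EIF1AD -1.47 ± 0.19, CNTD2 -1.44 ± 0.26, GLDN, the gliomedin gene, -1.44 ± 0.24, RLN3, the relaxin-3 gene, -1.33 ± 0.42 (adjusted p = 0.028) and REP15 -1.29 ± 0.35. Whether the genes with large standard errors here were expressed above background is unknown. A second measurement of SLMO2 under the name C20ORF45 differed by -0.061 and did not pass.

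Lists of mitosis and DNA replication genes fell in siMock, the first from 2 mM on and the second at each dose. All 30 mitosis genes fell at 5 mM, also when adjusted over the list alone (median difference -0.715, camera adjusted p = 1.36e-23). Among them were the phosphatase gene CDC25C (-1.11 ± 0.05), the kinase gene PLK1 (-1.07 ± 0.16), the kinesin gene KIF20A (-1.05 ± 0.03) and cyclin B2, CCNB2 (-1.02 ± 0.03). At 2 mM 14 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.082, adjusted p = 0.00153). At 0.5 mM 5 rose and 3 fell (the same adjusted over the list alone) with a median of -0.005 (adjusted p = 0.99). Of the 35 DNA replication genes, 25 fell and 1 rose at 0.5 mM (27 and 1 adjusted over the list alone; median -0.182, adjusted p = 2.15e-17). Large falls there were those of CHAF1A of the chromatin assembly factor (-1.26 ± 0.17) and the licensing factor gene CDC6 (-1.20 ± 0.15). At 2 mM 16 fell and 3 rose (18 and 3 adjusted over the list alone; median -0.103). At 5 mM 29 fell and 1 rose (the same adjusted over the list alone; median -0.271), for example thymidylate synthase, TYMS (-0.72 ± 0.03), and the helicase subunit gene MCM5 (-0.58 ± 0.04). CDK inhibitor and growth arrest genes rose as a list at 0.5 mM, with 11 of 19 higher and none lower (12 and 1 adjusted over the list alone; median 0.127, adjusted p = 0.000105). At 2 mM 8 were higher and 3 lower (the same adjusted over the list alone; median 0.055, adjusted p = 0.0378; adjusted p = 0.123 with an estimated correlation). At 5 mM the list was not called (median 0.134, adjusted p = 0.134). CDKN1A, the gene of p21, rose by 0.17 ± 0.02 at 0.5 mM and 0.36 ± 0.02 at 2 mM. MXD1, a MYC antagonist gene, rose by 1.25 ± 0.07 at 5 mM, and CDKN2A, which encodes p16 and ARF, fell by 1.66 ± 0.10 at 5 mM. Ribosome biogenesis genes fell at each dose, 14, 21 and 19 of 29 (17, 21 and 20 adjusted over the list alone), while 1, 2 and 3 rose (2, 2 and 3 adjusted over the list alone; medians -0.103, -0.194 and -0.203). PPRC1 (-0.62 ± 0.03), RRS1 (-0.45 ± 0.05) and NOLC1 (-0.36 ± 0.04) were examples at 5 mM.

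Metallothionein genes, which encode metal-binding proteins, rose with dose in siMock. At each dose 8 of 9 rose and 0 fell, also adjusted over the list alone, and the median difference was 0.3 at 0.5 mM, 0.815 at 2 mM and 1.139 at 5 mM (adjusted p = 1.16e-07). At 5 mM MT1H rose by 2.30 ± 0.24, MT2A by 1.66 ± 0.09, MT1X by 1.47 ± 0.03 and MT1F by 1.15 ± 0.02. Of 23 histone genes, 15 rose at 2 mM and 15 at 5 mM, while 2 and 4 fell (16 and 15 rose, and 2 and 4 fell, adjusted over the list alone; medians 0.283 and 0.455, adjusted p = 7.79e-05 and 0.000233). HIST1H4H (2.83 ± 0.27), HIST1H2AC (1.73 ± 0.14), HIST1H3D (1.68 ± 0.33) and HIST1H2BD (1.27 ± 0.02) were examples at 5 mM. At 0.5 mM 10 histone genes rose and 4 fell (12 and 4 adjusted over the list alone; median 0.111, adjusted p = 0.0402), with adjusted p = 0.0754 with an estimated correlation. Histone, HLA and metallothionein genes belong to families of near-identical copies, so which copy a probe measured is uncertain.

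Antigen presentation genes rose at 0.5 and 2 mM, with 10 of 16 higher at either dose and 2 and 4 lower (the same counts adjusted over the list alone; medians 0.231 and 0.148, adjusted p = 1.18e-06 and 0.00289). HLA-DPA1 rose by 1.84 ± 0.12 at 0.5 mM, with the immunoproteasome gene PSMB9 (0.71 ± 0.20) and the MHC class II genes HLA-DMB (0.61 ± 0.03) and HLA-DRA (0.47 ± 0.03). At 5 mM the list was not called (adjusted p = 0.291), with 9 genes higher and 5 lower (9 and 6 adjusted over the list alone), among them TAPBP, the tapasin gene, at -1.19 ± 0.11. Interferon-stimulated genes passed at 0.5 mM alone of the siMock doses, with 9 of 24 higher and 1 lower (the same adjusted over the list alone; median 0.058, adjusted p = 0.0034). IFI27 (0.93 ± 0.15), IFI6 (0.65 ± 0.03) and ISG15 (0.35 ± 0.03) were examples, while at 5 mM OAS3 (-1.20 ± 0.08) and IFIT2 (-1.16 ± 0.31) fell. Neuronal genes rose as a list at all doses, 12, 11 and 12 of 21 higher (13, 11 and 12 adjusted over the list alone) and 1, 2 and 1 lower (the same adjusted over the list alone; medians 0.17, 0.183 and 0.242). At 5 mM RUNDC3A (2.43 ± 0.19), the microtubule regulator gene STMN2 (2.33 ± 0.15), the neurosecretory gene VGF (1.94 ± 0.05) and SYT11, a synaptotagmin gene (1.62 ± 0.08), were examples. Of 20 immediate early genes 10 rose at 0.5 mM and 11 at 2 mM, while 1 and 2 fell (12 and 11 rose, and 1 and 2 fell, adjusted over the list alone; medians 0.083 and 0.153). EGR2 (0.95 ± 0.09) and JUN (0.86 ± 0.03) were examples at 2 mM. At 5 mM 11 were higher and 2 lower (the same adjusted over the list alone; median 0.178, adjusted p = 0.0125; adjusted p = 0.0698 with an estimated correlation). Wnt targets and stem cell genes were called at 0.5 mM only (9 of 19 higher and 3 lower, 12 and 3 adjusted over the list alone, median 0.136, adjusted p = 0.00161; adjusted p = 0.0639 with an estimated correlation). The Wnt targets NKD1 (2.34 ± 0.20), SP5 (2.21 ± 0.31), the receptor gene EPHB3 (1.76 ± 0.19) and NOTUM (1.33 ± 0.05) rose at 5 mM, where the list was not called (median 0.095, adjusted p = 0.276).

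Most metabolic lists were not called in siMock. Cholesterol synthesis genes had medians of 0.005, -0.035 and -0.032, with no call, and 5 of 25 rose and 10 fell at 5 mM (the same adjusted over the list alone). Fatty acid and triglyceride synthesis genes were not called (adjusted p = 0.533 at 5 mM), with 10 of 21 higher and 4 lower there (the same adjusted over the list alone). Examples were DGAT2 higher (1.66 ± 0.38) and the fatty acid synthase gene FASN (-0.53 ± 0.04) and the desaturase gene SCD (-0.58 ± 0.03) lower. Of 21 glycolysis genes 7 rose and 11 fell at 5 mM (the same adjusted over the list alone; median -0.087, adjusted p = 0.412). The glucose transporter gene SLC2A3 rose at each dose, by 0.59, 1.17 and 1.28. Acetyl-CoA and citrate supply genes (median -0.077 at 5 mM, adjusted p = 0.276) and oxidative phosphorylation genes (median 0.013, adjusted p = 0.71) showed no list call. Butyrate transport and beta-oxidation genes were higher at 0.5 and 2 mM, 10 of 22 at each and 1 and 4 lower (12 higher at each, and 1 and 4 lower, adjusted over the list alone; medians 0.09 and 0.103, adjusted p = 0.014 and 0.045). Both calls ended with an estimated correlation (adjusted p = 0.0938 and 0.192 with an estimated correlation). Unfolded protein and integrated stress response genes were lower as a list at 0.5 mM (6 of 22 lower and 2 higher, the same adjusted over the list alone; median -0.041, adjusted p = 0.0276; adjusted p = 0.107 with an estimated correlation). They also were at 2 mM (11 and 4, the same adjusted over the list alone; median -0.059, adjusted p = 0.045; adjusted p = 0.191 with an estimated correlation). At 5 mM the list was not called, with 11 lower and 6 higher (the same adjusted over the list alone; median -0.138, adjusted p = 0.085). The histone deacetylase list (median 0.124 at 5 mM, adjusted p = 0.452) and the acetyltransferase list (median -0.062, adjusted p = 0.71) were not called at any dose. The deacetylase list covers the whole enzyme family, not all of which acts on histones. Of it SIRT4 (1.44 ± 0.12) and HDAC10 (2.04 ± 0.46) rose at 5 mM, and of the acetyltransferases MYST1, now KAT8 (-0.47 ± 0.04), fell.

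With only the arrays compared in the fit, 0.5 mM changed 1519 genes in siMock, and 13 of the 16 genes named there by size stayed past the threshold, while 3 were lost without at least 1 array. Measured against 0.5 mM in place of untreated arrays, a comparison chosen after seeing the data, 2 mM changed 3924 genes.

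**Figure D3:**
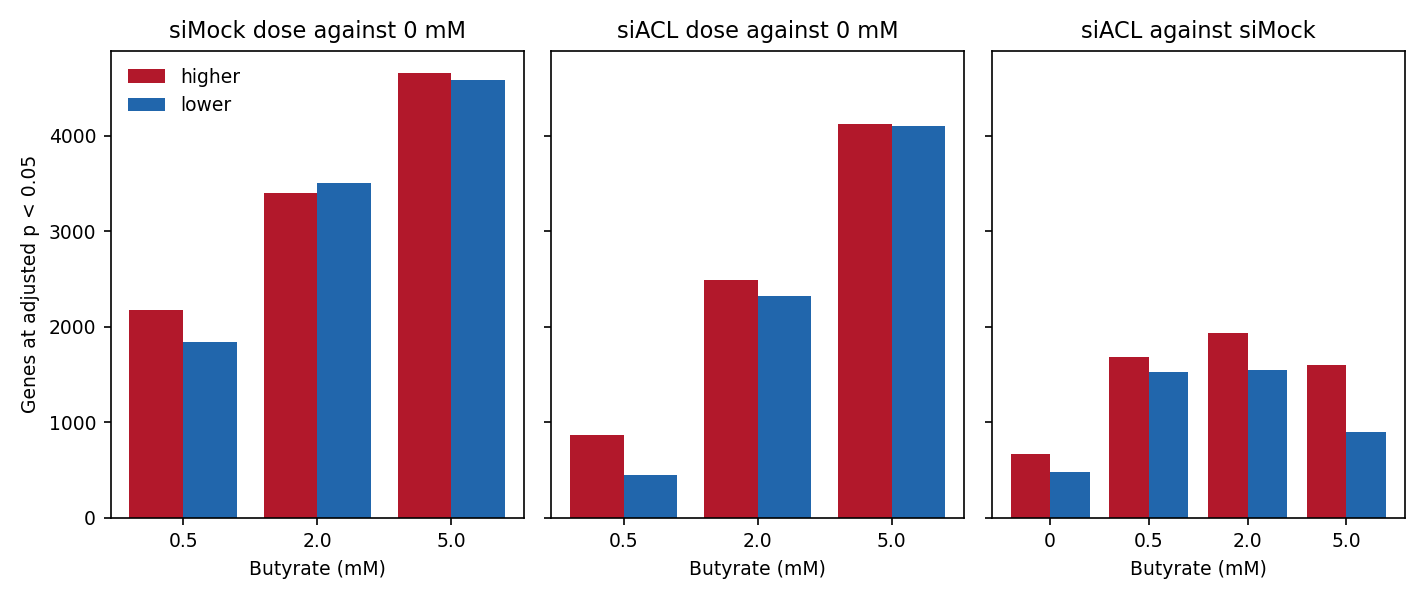
Bars count the genes (vertical axis) that were higher (red) or lower (blue) at adjusted p under 0.05 in each comparison, by butyrate dose (horizontal axis, mM). Counts rise with dose from 2180 higher and 1842 lower to 4655 and 4582 in siMock, and from 870 and 445 to 4123 and 4099 in siACL.

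The same doses were then compared in cells depleted of ATP citrate lyase. In siACL 1315 genes changed at 0.5 mM (870 higher and 445 lower), 4816 at 2 mM (2491 and 2325) and 8222 at 5 mM (4123 and 4099). As in siMock, all 30 mitosis genes were lower at 5 mM and metallothionein and neuronal genes were higher at all doses. Histone genes were not called higher as a list at any dose, though their median at 5 mM was 0.172 (adjusted p = 0.0917). The largest rises were those of CST1 (3.87 ± 0.14 at 5 mM), DKK4 (3.65 ± 0.27), PAGE4 (3.42 ± 0.22), SCGB2A1, a secretoglobin gene (3.40 ± 0.22), and ODZ3 (3.36 ± 0.18). SLC7A11, the cystine transporter gene, fell by 3.23 ± 0.25, ahead of SLCO1B3, an organic anion transporter gene (-2.95 ± 0.29), GLDN (-2.72 ± 0.24), GCNT3 (-2.72 ± 0.27) and ZBED2 (-2.53 ± 0.28). At 2 mM CST1 (3.19 ± 0.14), HLA-DPA1 (3.10 ± 0.12), SCGB2A1 (2.95 ± 0.22), APOD, the apolipoprotein D gene (2.94 ± 0.24), and PAGE4 (2.90 ± 0.22) rose most. SLC7A11 (-2.65 ± 0.25), GCNT3 (-2.63 ± 0.27), PPIL6 (-2.42 ± 0.31), GLDN (-2.36 ± 0.24) and SLCO1B3 (-2.23 ± 0.29) fell most. At 0.5 mM the rises were in AFAP1L2 (2.20 ± 0.06), EFHD1 (1.81 ± 0.15), CALHM3 (1.66 ± 0.21), FXYD4 (1.59 ± 0.18) and SHD (1.57 ± 0.11). The falls were in KRTAP2-2 (-1.60 ± 0.24), WDR65 (-1.10 ± 0.26), SAMD3 (-0.90 ± 0.22), GLDN (-0.81 ± 0.24, adjusted p = 0.046) and RASL11B (-0.65 ± 0.13).

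Mitosis genes in siACL had a median of -0.063 at 0.5 mM (5 of 30 lower and 0 higher, 9 and 0 adjusted over the list alone, adjusted p = 2.2e-08). At 2 mM it was -0.011 (4 higher and 3 lower, the same adjusted over the list alone, adjusted p = 0.735) and at 5 mM -0.301 (adjusted p = 1.78e-15). PLK1 (-0.58 ± 0.16), HMMR (-0.57 ± 0.02) and cyclin A2, CCNA2 (-0.56 ± 0.04), were examples at 5 mM. DNA replication genes fell at all doses, 11, 22 and 20 of 35 (13, 23 and 20 adjusted over the list alone). Of the rest, 0, 2 and 4 rose (the same adjusted over the list alone; medians -0.084, -0.126 and -0.14), with TYMS (-0.41 ± 0.03) and MCM2 (-0.36 ± 0.03) as examples at 5 mM. Ribosome biogenesis genes had a median of 0.001 and a mean of -0.002 at 0.5 mM (adjusted p = 0.953). Of them 16 and 21 of 29 fell and 1 and 1 rose at 2 and 5 mM (19 and 21 fell, and 2 and 1 rose, adjusted over the list alone; medians -0.107 and -0.205). Metallothionein medians were 0.112, 0.561 and 1.082, with 4, 8 and 9 of 9 higher and none lower at the doses in turn, also adjusted over the list alone. Histone genes were lower as a list at 0.5 mM (4 lower and 1 higher, 5 and 1 adjusted over the list alone; median -0.036, adjusted p = 0.00922). They were not called at 2 mM (median 0.026, adjusted p = 0.994) or 5 mM (median 0.172, adjusted p = 0.0917). At 5 mM 10 rose and 4 fell (11 and 5 adjusted over the list alone), with HIST1H4H higher by 2.53 ± 0.27. Cholesterol synthesis genes rose as a list at 0.5 mM (3 higher and 1 lower, 5 and 1 adjusted over the list alone; median 0.041, adjusted p = 0.00542). They also did at 2 mM (6 and 1, 9 and 1 adjusted over the list alone; median 0.052, adjusted p = 0.0128). At 5 mM 19 of 25 fell and 3 rose (the same adjusted over the list alone; median -0.208, adjusted p = 8.18e-05), among them ACAT2 (-0.52 ± 0.03) and CYP51A1 (-0.41 ± 0.04). Unfolded protein and integrated stress response genes fell at 2 and 5 mM, 11 and 13 of 22 lower and 3 and 2 higher (11 and 13 lower, and 3 and 3 higher, adjusted over the list alone; medians -0.13 and -0.255, adjusted p = 0.000276 and 0.000213). SLC7A11, the glutathione-degrading enzyme gene CHAC1 (-1.36 ± 0.31), DDIT4 (-0.78 ± 0.03) and TRIB3 (-0.71 ± 0.04) were examples at 5 mM. Growth arrest genes were called higher as a list at 2 mM alone of the siACL doses (7 of 19 higher and 0 lower, 8 and 0 adjusted over the list alone; median 0.072, adjusted p = 0.00706). Butyrate transport and beta-oxidation genes were so called at 5 mM alone (11 of 22 higher and 5 lower, 12 and 5 adjusted over the list alone; median 0.143, adjusted p = 0.0479; adjusted p = 0.204 with an estimated correlation). Antigen presentation genes rose at 0.5 and 2 mM, 6 and 10 of 16 higher and 0 and 3 lower (8 and 11 higher, and 1 and 3 lower, adjusted over the list alone; medians 0.081 and 0.272). At 5 mM 8 were higher and 4 lower (9 and 4 adjusted over the list alone; median 0.259, adjusted p = 0.0479; adjusted p = 0.0697 with an estimated correlation). Neuronal genes rose in 7, 10 and 11 of 21 cases and fell in 1, 1 and 2 (8, 11 and 11 rose, and 1, 1 and 2 fell, adjusted over the list alone), with called medians of 0.156, 0.209 and 0.236. Immediate early genes rose in 9, 14 and 13 of 20 cases and fell in 0, 2 and 3 (10, 14 and 13 rose, and 0, 2 and 3 fell, adjusted over the list alone), with called medians of 0.094, 0.215 and 0.187. Wnt targets and stem cell genes had called medians of 0.112 and 0.201 at 0.5 and 2 mM, with 9 and 13 of 19 higher and 0 and 4 lower (12 and 13 higher, and 1 and 4 lower, adjusted over the list alone). At 5 mM 12 Wnt targets were higher and 6 lower (the same adjusted over the list alone; median 0.182, adjusted p = 0.0479; adjusted p = 0.24 with an estimated correlation). With only the arrays compared, 0.5 mM changed 264 genes in siACL and kept 6 of the 10 named there by size, and with array weights it changed 2066. Without replicate 2 of the 0.5 mM siACL arrays it changed 870, and 3 of the 10 were lost without at least 1 array.

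**Figure D4:**
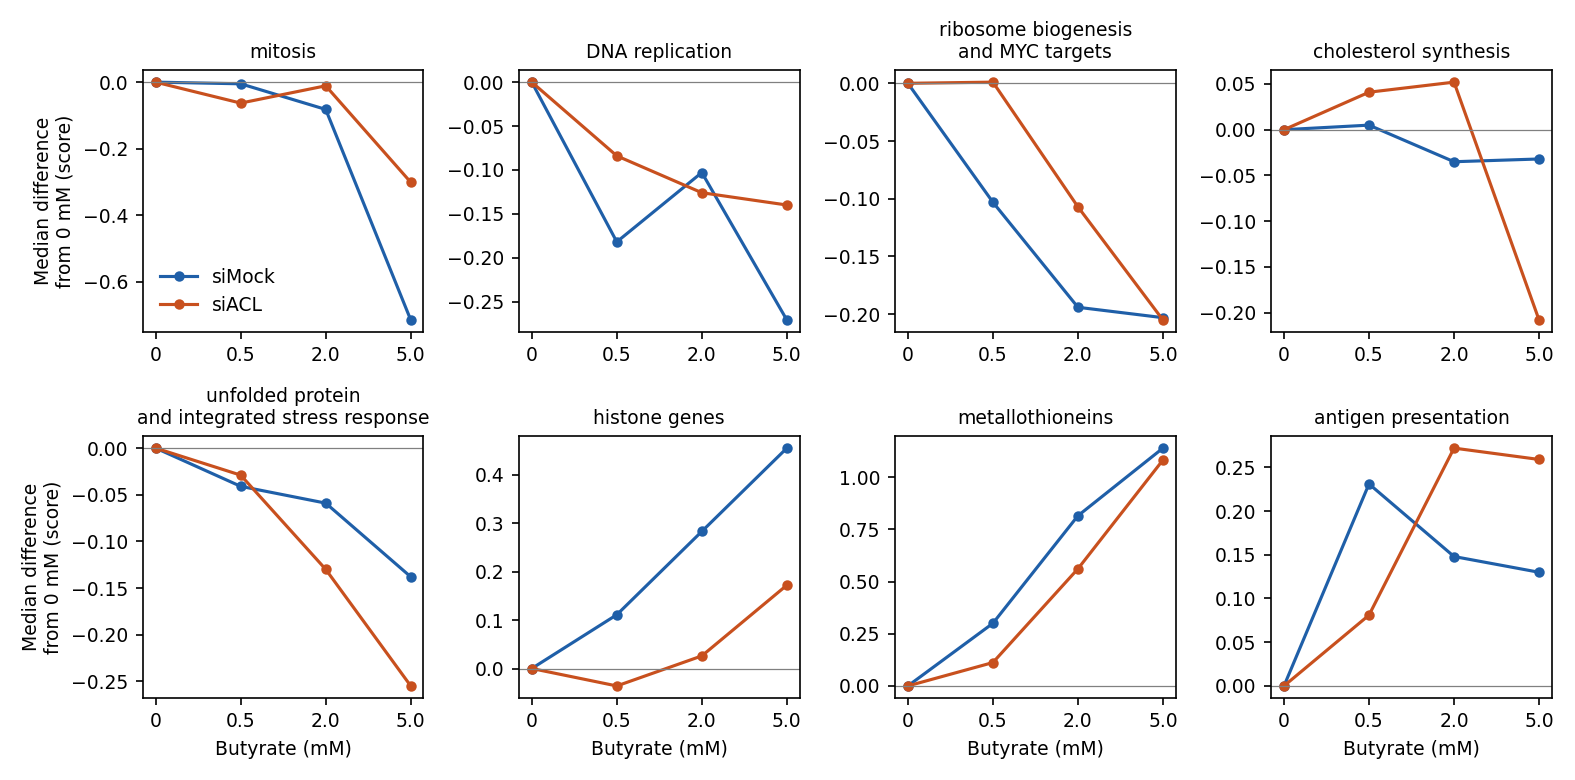
Each panel gives the median difference from the untreated arrays of the same arm (vertical axis, score, with its own scale in each panel) over the measured members of 1 gene list, by butyrate dose (horizontal axis, mM, evenly spaced), in siMock (blue) and siACL (orange). At 5 mM the mitosis median was -0.715 in siMock and -0.301 in siACL, and the histone gene medians were 0.455 and 0.172.

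Butyrate changes shared by both arms mostly had the same direction, and the slope of the siACL change on the siMock change was below 1 at each dose. Of the genes called at 5 mM, 3487 rose and 3371 fell in both arms and 24 and 39 went opposite ways, where independent lists of these sizes would share 1056.2 and 1033.5. At 0.5 mM 682 rose and 297 fell in both, against 104.4 and 45.1. Across genes, which are not independent replicates, the changes correlated at r = 0.308 at 0.5 mM, 0.575 at 2 mM and 0.758 at 5 mM. Over the 9763 genes with a mean score above 0, a set chosen after seeing the data, r was 0.684, 0.832 and 0.91. In that set the slope of the siACL change on the siMock change, with replicate noise taken out, was 0.481 ± 0.022 at 0.5 mM, 0.65 ± 0.017 at 2 mM and 0.768 ± 0.011 at 5 mM (jackknife SE). Within an arm the doses share untreated arrays, so unchanged groups were simulated against the same arrays. The changes at 0.5 and 5 mM correlated at r = 0.565 in siMock (simulated 0.501), with a covariance of 0.082 (simulated 0.021), and at 0.468 in siACL (simulated 0.5), with 0.046 (simulated 0.021). In siMock 1736 genes rose and 1416 fell at both doses (558.4 and 464.5 for independent lists), and in siACL 732 and 350 (197.4 and 100.4). Part of the excess may come from the shared untreated arrays.

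The next question was what the knockdown alone changed. Without butyrate 1147 genes differed between siACL and siMock, 672 higher and 475 lower in siACL. Cholesterol synthesis, stress response, ribosome biogenesis and histone genes were higher in siACL as lists, and the metallothionein list was lower. Among the largest rises were ZNF264 (3.82 ± 0.17), LRRC26 (2.97 ± 0.61, adjusted p = 0.0072), the keratin gene KRT13 (2.24 ± 0.21), ARHGDIB (1.68 ± 0.10), CHAC1 (1.65 ± 0.31), EBI3, a cytokine subunit gene (1.64 ± 0.36), SLC7A11 (1.58 ± 0.25) and TSPYL4 (1.52 ± 0.39, adjusted p = 0.027). As stated above, ZNF264 and ARHGDIB were low in untreated siMock alone of all groups. Among the lower genes were KRT18P44, a keratin pseudogene (-1.43 ± 0.34), IL4I1 (-1.24 ± 0.35), the glutamate transporter gene SLC1A7 (-1.22 ± 0.31), the chloride channel gene CLCN1 (-1.21 ± 0.34) and LEFTY2, a Nodal antagonist gene (-1.07 ± 0.21). So were CD1B (-0.97 ± 0.28, adjusted p = 0.047), CCDC87 (-0.94 ± 0.16) and LRRC32 (-0.88 ± 0.10, adjusted p = 5.6e-05).

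Of 25 cholesterol synthesis genes 10 were higher and 1 lower in untreated siACL (17 and 1 adjusted over the list alone; median 0.122, adjusted p = 3.12e-13). HMGCS1, which makes HMG-CoA, was higher by 0.36 ± 0.03, with INSIG1 (0.31 ± 0.04) and IDI1 (0.21 ± 0.04). Unfolded protein and integrated stress response genes were higher in 13 of 22 cases and lower in none (16 and 1 adjusted over the list alone; median 0.129, adjusted p = 1.32e-12). DDIT3, the CHOP gene (0.33 ± 0.06), and DDIT4 (0.31 ± 0.03) were among them beside CHAC1 and SLC7A11. Ribosome biogenesis genes were higher in 9 of 29 and lower in none (11 and 0 adjusted over the list alone; median 0.071, adjusted p = 3.18e-06), for example RRP12 (0.21 ± 0.03). Among fatty acid and triglyceride synthesis genes 7 of 21 were higher and none lower (9 and 1 adjusted over the list alone; median 0.05, adjusted p = 8.81e-05), with FASN (0.21 ± 0.04), ELOVL6 (0.19 ± 0.02) and LPIN1 (0.18 ± 0.03). Histone genes were higher in 8 of 23 and lower in 1 (10 and 1 adjusted over the list alone; median 0.196, adjusted p = 1.61e-07), for example HIST1H2AC (1.20 ± 0.14) and HIST1H2BD (0.51 ± 0.02). Metallothioneins were lower in 3 of 9 and higher in none (4 and 0 adjusted over the list alone; median -0.102, adjusted p = 0.00577), including MT1X (-0.17 ± 0.03). Growth arrest genes (3 higher and 1 lower of 19, 5 and 1 adjusted over the list alone; median 0.059, adjusted p = 0.0101; adjusted p = 0.0531 with an estimated correlation) were called only with the preset correlation. DNA replication genes (0 higher and 1 lower of 35, the same adjusted over the list alone; median -0.027, adjusted p = 0.015; adjusted p = 0.0516 with an estimated correlation) were too. ACSS2, the cytosolic enzyme that makes acetyl-CoA from acetate, was higher by 0.18 ± 0.02, and SLC25A1, the mitochondrial citrate carrier gene, lower (-0.10 ± 0.03). The acetyl-CoA and citrate supply list as a whole did not differ (median -0.026, adjusted p = 0.813). With only the untreated arrays in the fit, 27 genes passed and 4 of the 16 genes named by size did, and 6 of the 16 were lost without at least 1 array. The count was 690, 724 and 734 without replicate 1, 2 or 3 of untreated siACL and 737 without replicate 3 of untreated siMock.

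With butyrate, more genes differed between siACL and siMock than without it. At 0.5 mM 3213 genes differed (1683 higher and 1530 lower in siACL), at 2 mM 3479 (1931 and 1548) and at 5 mM 2493 (1600 and 893). Cholesterol synthesis genes were higher in siACL at 0.5 mM (19 of 25 higher and 1 lower, 19 and 1 adjusted over the list alone; median 0.183, adjusted p = 1.87e-12). They were higher at 2 mM too (20 and 1, 21 and 2 adjusted over the list alone; median 0.211, adjusted p = 6.38e-16) and not called at 5 mM (median -0.038, mean 0.019, adjusted p = 0.937). HMGCS1 was higher by 0.45 ± 0.03 at 0.5 mM and 0.49 ± 0.03 at 2 mM. Ribosome biogenesis genes were higher at 0.5 mM (21 of 29 higher and 0 lower, 24 and 0 adjusted over the list alone; median 0.174) and 2 mM (17 and 1, 20 and 1 adjusted over the list alone; median 0.127). Stress response genes were higher at 0.5 mM (15 of 22 higher and 0 lower, also adjusted over the list alone; median 0.209) and 2 mM (9 and 1, also adjusted over the list alone; median 0.124). SLC7A11 differed by 2.56 ± 0.25 and CHAC1 by 1.29 ± 0.31 at 0.5 mM. At 5 mM all 30 mitosis genes were higher in siACL than in siMock, also adjusted over the list alone (median 0.349, adjusted p = 7.77e-50), for example CDC25C (0.70 ± 0.05), PLK1 (0.61 ± 0.16) and CCNB2 (0.50 ± 0.03). So were 21 of 35 DNA replication genes with 0 lower (27 and 0 adjusted over the list alone; median 0.126). At 0.5 mM the mitosis median was -0.091 (18 lower and 0 higher, 20 and 1 adjusted over the list alone) and at 2 mM 0.052 (8 higher and 0 lower, 11 and 0 adjusted over the list alone). DNA replication genes had called medians of 0.077 and -0.048 at these doses (14 and 1 higher and 2 and 10 lower; 15 and 1 higher and 2 and 10 lower adjusted over the list alone), with CDC6 higher by 1.42 ± 0.15 at 0.5 mM. Metallothioneins were lower in siACL, 5, 6 and 4 of 9 with none higher (8, 6 and 4 lower adjusted over the list alone; medians -0.25, -0.367 and -0.31), for example MT2A at -0.80 ± 0.09 at 2 mM. Histone genes, higher without butyrate, were not called at 0.5 mM (adjusted p = 0.301). They were lower in siACL at 2 mM (8 lower and 2 higher, the same adjusted over the list alone; median -0.066, but -0.036 and not called, adjusted p = 0.0733, without replicate 3 of siMock at 2 mM) and 5 mM (7 and 3, 9 and 3 adjusted over the list alone; median -0.166, adjusted p = 0.00204), with HIST2H2AA3 at -0.48 ± 0.04. At 0.5 mM antigen presentation genes were lower in siACL (8 of 16 lower and 1 higher, 10 and 1 adjusted over the list alone; median -0.14), including HLA-DPA1 (-0.86 ± 0.12). Neuronal genes were too (7 of 21 lower and 0 higher, also adjusted over the list alone; median -0.103), including STMN2 (-0.51 ± 0.15). Interferon-stimulated genes were called lower at 0.5 mM (6 lower and 1 higher, the same adjusted over the list alone; median -0.056, adjusted p = 0.0301; adjusted p = 0.0692 with an estimated correlation; -0.035 without replicate 3 of siMock at 0.5 mM). They were called higher at 5 mM (5 higher and 1 lower, the same adjusted over the list alone; median 0.055, adjusted p = 0.0291; adjusted p = 0.063 with an estimated correlation). Epithelial junction and keratin genes were higher in siACL at 2 mM (13 of 25 higher and 2 lower, also adjusted over the list alone; median 0.142) and 5 mM (9 and 0, 10 and 0 adjusted over the list alone; median 0.105). KRT7 was higher by 1.18 ± 0.24 and 1.48 ± 0.24. Fits on only the arrays compared called 1548, 765 and 413 genes at 0.5, 2 and 5 mM.

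The last comparison tested directly whether the change with butyrate differed between the arms, as the siACL change minus the siMock change. It is a difference of changes in score. Where the arms start from different scores, it need not hold for transcript amounts. This interaction was called for 564 genes at 0.5 mM (252 with a higher change in siACL and 312 with a lower one), 1124 at 2 mM (628 and 496) and 1608 at 5 mM (999 and 609). At 5 mM mitosis and DNA replication genes fell less in siACL, histone genes and metallothioneins rose less, and cholesterol synthesis and stress response genes changed in a more negative direction. Of 30 mitosis genes 29 had a positive and none a negative interaction at 5 mM, and all were positive adjusted over the list alone (median 0.381, adjusted p = 3.1e-47). Examples were CDC25C (0.72 ± 0.07), CCNB2 (0.51 ± 0.04), the survivin gene BIRC5 (0.51 ± 0.05) and KIF20A (0.50 ± 0.05). Of 35 DNA replication genes 16 had a positive and none a negative one (24 and 0 adjusted over the list alone; median 0.17), for example RRM2, a ribonucleotide reductase subunit gene (0.49 ± 0.07). Histone genes had a negative interaction at each dose, 7, 11 and 10 of 23 negative (11, 11 and 11 adjusted over the list alone) and 1, 0 and 2 positive (1, 0 and 3 adjusted over the list alone; medians -0.141, -0.259 and -0.391). HIST1H2AC had -1.21 ± 0.20 at 2 mM and -1.45 ± 0.20 at 5 mM. The histone list was already higher in untreated siACL, which enters each of these values. Metallothionein interactions were negative for 1, 6 and 3 genes and positive for 0, 0 and 1 (2, 6 and 4 negative, and 0, 0 and 1 positive, adjusted over the list alone; medians -0.171, -0.242 and -0.119), with MT2A at -0.70 ± 0.13 at 2 mM. Cholesterol synthesis genes had a positive median interaction at 2 mM (6 positive and 0 negative, 9 and 0 adjusted over the list alone; median 0.074, adjusted p = 0.000166). At 5 mM it was negative (1 and 9, 1 and 11 adjusted over the list alone; median -0.142, adjusted p = 8.72e-07). At 5 mM HMGCS1 (-0.33 ± 0.04) and IDI1 (-0.30 ± 0.05) were negative. Stress response genes had 8 negative and 1 positive interactions of 22 at 5 mM (13 and 2 adjusted over the list alone; median -0.126, adjusted p = 5.11e-05), including TRIB3 (-0.30 ± 0.05). Cholesterol synthesis and stress response genes were also already higher in untreated siACL, which enters these values, and at 5 mM neither list differed by a call between siACL and siMock (medians -0.038 and 0.009, adjusted p = 0.937 and 0.195).

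Among single genes, ZBED2 had an interaction of 3.30 ± 0.39 at 2 mM, where it differed by -3.45 in siMock and by -0.15, without passing, in siACL. At 5 mM its interaction was 1.5 ± 0.39. ARMC4 (1.72 ± 0.28), GPR110 (1.44 ± 0.17), SLC22A18AS (1.38 ± 0.26) and SNTB1, a syntrophin gene (1.63 ± 0.16), were also positive at 2 mM. SNCG (1.40 ± 0.28) and the interferon-inducible gene EPSTI1 (1.64 ± 0.28) were positive at 5 mM. Negative interactions at 5 mM included those of SLC7A11 (-2.03 ± 0.35), CHAC1 (-1.76 ± 0.44), TSPYL4 (-2.19 ± 0.55), the cadherin gene CDH13 (-1.97 ± 0.22), LRRC26 (-2.91 ± 0.87, adjusted p = 0.045) and ZNF264 (-3.93 ± 0.24). All of these but CDH13 were already higher in untreated siACL and not called between the arms at 5 mM (SLC7A11 -0.45, CHAC1 -0.12, TSPYL4 -0.67, LRRC26 0.06 and ZNF264 -0.11), so their interactions rest largely on the untreated difference. The synaptic vesicle gene SYP rose by 2.77 in siMock and 0.84 in siACL at 2 mM, an interaction of -1.93 ± 0.31. At 0.5 mM CNTNAP2 (-1.30 ± 0.17), ARHGDIB (-1.79 ± 0.15) and RASL11B (-1.78 ± 0.18) were negative, the first 2 also higher in untreated siACL and not called between the arms at 0.5 mM, and GCNT3 (1.47 ± 0.38, adjusted p = 0.043) and CHAF1A (1.16 ± 0.24) positive. Fits on only the arrays compared called 235, 503 and 1024 genes and kept 7, 11 and 12 of the 16 named by size at 0.5, 2 and 5 mM, while 6, 5 and 7 of the 16 were lost without at least 1 array, and the count at 0.5 mM was 354 without replicate 2 of siMock at 0.5 mM and 373 without replicate 3 of untreated siACL.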

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

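The tests of replicate noise and of displaced untreated arrays in the siACL slope, the comparison of slopes between doses, the nearness to lower doses, the reassigned residuals and the count of genes set apart in each group were chosen only after the result was seen. The other tests here were set beforehand.

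The results below are differences between the arms in the change with butyrate, each tested as an interaction. At 0.5 mM 564 genes differed in their change, at 2 mM 1124 and at 5 mM 1608. Knockdown labels were exchanged among the untreated arrays and among the arrays of the dose in 100 splits. As many genes as in the real split were called in 7 splits at 0.5 mM (564, highest other split 1590), 4 at 2 mM (1124 and 1601) and 2 at 5 mM (1608 and 2519), the real one included. The share at 0.5 mM is not under 0.05, so by the rule set beforehand it counted for chance there. Apart from the real one, all splits that reached these counts kept siACL and siMock apart at the dose. They therefore hold the difference between the arms itself and do not measure chance. Splits that mixed the arms at both doses gave at most 4 genes. Residuals of a model without interaction were therefore reassigned among the 12 arrays, with the differences of arm and dose kept. Counting the real order, 2 of 100 orders gave as many genes at 0.5 mM (highest other 1018), 2 at 2 mM (1929) and 1 at 5 mM (61). These shares are under 0.05 and argue against chance. At 0.5 and 2 mM another order called more genes than the real one, so chance is not excluded there.

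At 0.5 mM the interaction was negative for the lists of mitosis (median -0.071), growth arrest (-0.068), histone genes (-0.141), metallothioneins (-0.171), interferon-stimulated genes (-0.139) and antigen presentation (-0.123). It was positive for DNA replication (0.102) and ribosome biogenesis (0.073). Calls that were lost with an estimated correlation were stress response (0.048, adjusted p = 0.0981 with an estimated correlation), hypoxia targets (-0.037, adjusted p = 0.0664 with an estimated correlation) and antioxidant genes (0.082, adjusted p = 0.0981 with an estimated correlation; 0.038 without replicate 1 of untreated siACL). At 2 mM the interaction was positive for mitosis (0.075), ribosome biogenesis (0.068), cholesterol synthesis (0.074) and epithelial genes (0.122), and negative for histone genes (-0.259) and metallothioneins (-0.242). The Wnt list (0.056) was called only with the preset correlation (adjusted p = 0.158 with an estimated correlation). At 5 mM it was positive for mitosis (0.381), DNA replication (0.17) and antigen presentation (0.112). The antigen presentation call at 5 mM was lost without replicate 3 of untreated siMock (0.067, adjusted p = 0.0904), of siMock at 5 mM (0.077, adjusted p = 0.0865) or of siACL at 5 mM (0.108, adjusted p = 0.0654). It was negative for cholesterol synthesis (-0.142), fatty acid synthesis (-0.072), histone genes (-0.391), metallothioneins (-0.119) and stress response (-0.126).

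Among single genes at 0.5 mM, the secretoglobin gene SCGB2A1 (1.47), GCNT3 (1.47), the Nodal antagonist gene LEFTY2 (1.17) and CHAF1A (1.16) had positive interactions. So did CNTD2 (1.58), EIF1AD (1.5), ZNF431 (1.31) and ZSCAN29 (1.13). Negative ones were those of ZNF264 (-3.43), ARHGDIB (-1.79), RASL11B (-1.78), BEX5 (-1.43), the autotaxin gene ENPP2 (-1.43), the sodium-calcium exchanger gene SLC8A2 (-1.37), the coagulation factor gene F10 (-1.33) and CNTNAP2 (-1.30). At 2 mM the natural killer receptor gene KLRC2 (1.35), ZBED2 (3.30), KRT18P44 (1.83), ARMC4 (1.72), SNTB1 (1.63), GPR110 (1.44) and SLC22A18AS (1.38) were positive. The innate sensor gene IFI16 (-2.11), ZNF264 (-3.54), EMR4P (-2.00), CHAC1 (-1.99), SYP (-1.93), ARHGDIB (-1.81), TMEM110 (-1.73) and DKK4 (-1.67) were negative. At 5 mM KRT18P44 (1.74), MXRA8 (1.72), EPSTI1 (1.64), ZBED2 (1.5), ABHD14B (1.46), the mitochondrial nucleotidase gene NT5M (1.44), SNCG (1.40) and PRTFDC1 (1.27) were positive. ZNF264 (-3.93), LRRC26 (-2.91), EMR4P (-2.50), TSPYL4 (-2.19), SLC7A11 (-2.03), CDH13 (-1.97), TMEM178 (-1.86) and CHAC1 (-1.76) were negative. Of the genes in this paragraph, ZNF264, ARHGDIB, SLC8A2, CNTNAP2, IFI16, CHAC1, LRRC26, TSPYL4 and SLC7A11 were already higher, and LEFTY2 and KRT18P44 lower, in untreated siACL and were not called between the arms at the dose given, so their interactions rest largely on the untreated difference.

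Butyrate changes were smaller in siACL than in siMock, most at 0.5 mM. Noise in the siMock differences would flatten the slope of siACL on siMock. However, the slope corrected for noise was 0.481 (jackknife SE 0.022) at 0.5 mM. Untreated siMock arrays displaced along the butyrate change would give the untreated difference a positive slope on the siMock change at 0.5 mM. That slope was 0.017 (SE 0.049). These slopes are over genes with a mean score above 0. A knockdown effect opposite to butyrate could offset a displacement, so the value does not exclude one. On the second principal component of all genes, untreated siACL (3.6) lay between untreated siMock (19.1) and siMock at 0.5 mM (-3.4). A uniformly weaker response in siACL met the bound set for it, with a slope of 0.779 (SE 0.016) from 0.5 to 5 mM. However, the slopes at 0.5 and 5 mM differed by 0.287 (SE 0.025), which a single factor for all doses on the score scale forbids. A single factor on transcript amounts need not give equal slopes of rank scores, so it is not decided by this difference. The SE of 0.025 treats the 2 slopes as independent, although both use the same untreated arrays, so it is approximate. Not all changes in score were smaller, since at 5 mM cholesterol synthesis (median -0.208 in siACL and -0.032 in siMock), stress response (-0.255 and -0.138) and ACLY (-0.50 and -0.21) fell more in siACL, both lists from a higher level in untreated siACL (0.122 and 0.129). With unequal starting scores, this need not hold for transcript amounts. A lower effective dose in the depleted cells stays open, because over genes with a mean score above 0 the root mean square difference put siACL nearer to siMock at the next lower dose (0.072 against 0.104 at 2 mM, 0.093 against 0.116 at 5 mM) while r was higher with the same dose (0.832 against 0.811, 0.91 against 0.901), and differences between culture batches were untested.

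In untreated siMock 3 genes lay at least 1 score below every array of all other groups: ZNF264 (gap 3.11), ARHGDIB (1.31) and SLC8A2 (1.05). In 100 simulated sets the highest count was 0, against 3. Each gene was drawn there from a normal curve around its mean over all arrays, with its own residual SD. The result argues against noise of that kind. A larger spread of these genes when near the array floor was not simulated, so floor noise is not excluded. Untreated siMock arrays that stand apart technically cannot be told apart from a change brought by either treatment, because 5 mM siMock also held 3 such genes (1 low and 2 high) and the other 6 groups 0. Low levels that any butyrate dose and the knockdown both lift may be a further explanation, which the design does not separate from the first.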

How the results depend on the processing

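Settings chosen only after the data were seen are the minimum difference, the 0.5 mM reference, genes with a mean score above 0, percentile ranks and all entries with or without a symbol. Counts of called genes in the 13 comparisons moved by no more than 1.5 times with the trend and robust prior, percentile ranks and all entries. With the replicate block they did too (for example 4022 to 3999 in siMock at 0.5 mM and 564 to 523 for the interaction at 0.5 mM), where residuals of arrays with the same number correlated at -0.04 to 0.03. With array weights the count for siACL at 0.5 mM moved to 2066, and the cause was not tested. Signal over background is unknown, so which weakly expressed genes were detected cannot be said.

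With only the arrays compared, which are fewer, counts fell to 1519 (siMock 0.5 mM), 264 (siACL 0.5 mM), 27, 1548, 765 and 413 (siACL against siMock at 0, 0.5, 2 and 5 mM) and 235, 503 and 1024 (interactions at 0.5, 2 and 5 mM). The stricter adjusted p under 0.01 left 2574 (siMock 0.5 mM), 656 (siACL 0.5 mM), 471, 1768, 2031 and 1253 (siACL against siMock) and 183, 463 and 800 (interactions). A difference of at least 0.25, also stricter, left 1222, 2987 and 5390 (siMock), 341, 1562 and 4163 (siACL), 326, 776, 844 and 575 (siACL against siMock) and 184, 422 and 597 (interactions). Genes with a mean score above 0 gave 876 for the interaction at 0.5 mM, and the cause was not tested. Against 0.5 mM, 2 mM changed 3924 genes in siMock and 2499 in siACL, where the reference itself had been treated.

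Without 1 array in turn, the count for siACL against siMock without butyrate ranged from 690 (without siACL_0mM replicate 1) to 972. It was 724 and 734 without siACL_0mM replicates 2 and 3 and 737 without siMock_0mM replicate 3. The interaction at 0.5 mM ranged from 354 (without siMock_0.5mM replicate 2) to 503 and was 373 without siACL_0mM replicate 3. The count for siACL at 0.5 mM ranged from 870 (without siACL_0.5mM replicate 2) to 954. Fewer arrays give fewer calls, and other causes were not tested. The other counts moved by no more than 1.5 times. ACLY in siMock at 0.5 mM, not called, went from -0.018 (without siMock_0mM replicate 1) to 0.001 (without siMock_0.5mM replicate 2) and was 0 without siMock_0mM replicate 2, a change of sign around -0.006 whose cause was not tested.

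The similarity of the changes in siMock and siACL rose with genes called in siMock, to r = 0.702, 0.826 and 0.891 at 0.5, 2 and 5 mM, and with a mean score above 0, to 0.684, 0.832 and 0.91. Between the doses of an arm it rose with a mean score above 0 to 0.686 in siMock and 0.621 in siACL. The cause was not tested. Without 1 array in turn it ranged over 0.281 to 0.295, 0.541 to 0.558 and 0.73 to 0.745 between the arms, and without 1 untreated array over 0.588 to 0.598 (siMock) and 0.498 to 0.501 (siACL) between the doses.

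Of 1440 calls of named genes, 24 were lost with array weights, 43 with the trend and robust prior, 47 with the replicate block, 513 with only the arrays compared and 312 without at least 1 array, and none of them turned direction in these settings. Of 138 list calls 28 were lost with an estimated correlation, 3 with the replicate block and 23 without at least 1 array, of which 20 were also lost with an estimated correlation. Not run were the background corrections, the median and cyclic loess normalizations, the detection filters, the mean of probes, single ACLY probes, the slide block and the 1.5-fold threshold, because the scores hold no signal, detection p, slide or probe; the authors' normalized table is the one used throughout.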

Other observations

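The tests of both explanations for the higher stress response and cholesterol genes in siACL were chosen only after the result was seen, while the splits of the arrays were set beforehand.

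Cell death, differentiation and stress lists gave the following values. Of 27 pro-apoptotic genes 14 rose and 7 fell in siMock at 5 mM (the same adjusted over the list alone; median 0.132, adjusted p = 0.384), for example the cytochrome c gene CYCS (0.97) up and the death receptor gene FAS (-1.19) down. In untreated siACL against siMock 5 were higher and 1 lower (the same adjusted over the list alone; median 0.046, adjusted p = 0.0435; adjusted p = 0.101 with an estimated correlation). Of 16 anti-apoptotic genes 7 rose and 5 fell in siMock at 5 mM (the same adjusted over the list alone; median 0.075, mean -0.039, adjusted p = 0.78), among them TNFAIP3 (1.25) and XIAP (-0.83). Of 27 p53 targets 10 rose and none fell in siMock at 2 mM (also adjusted over the list alone; median 0.061, adjusted p = 0.0149), including TP53INP1 (0.52). At 0.5 mM the p53 list was not called in siMock (5 higher and 3 lower, median 0.009, adjusted p = 0.544). At 5 mM it was not called either, with 7 higher and 9 lower (median -0.115, adjusted p = 0.653). In siACL at 2 mM 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.077, adjusted p = 0.00162). The p53 list was not called in siACL at 0.5 mM (1 higher and 0 lower, median 0.005, adjusted p = 0.578). Nor was it at 5 mM, with 6 higher and 10 lower (median -0.1, adjusted p = 0.35). Against siMock 8 were higher and none lower in untreated siACL (9 and 0 adjusted over the list alone; median 0.074, adjusted p = 3.87e-05), for example GDF15 (0.29). The p53 median against siMock was 0.098 at 0.5 mM (adjusted p = 0.0122) and 0.085 at 2 mM (adjusted p = 0.00442). At 5 mM the p53 median against siMock was 0.096 (adjusted p = 0.0445; adjusted p = 0.053 with an estimated correlation).

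Antioxidant and NRF2 targets were higher in siACL than in siMock without butyrate (3 of 21 higher and none lower, 7 and 2 adjusted over the list alone; median 0.067, adjusted p = 0.00199). At 0.5 mM 12 were higher and 2 lower (the same adjusted over the list alone; median 0.136), with AKR1B10 at 2.06. The change in siACL at 0.5 mM had a median of 0.058 (adjusted p = 0.00922; adjusted p = 0.0789 with an estimated correlation; 0.037 without replicate 1 of untreated siACL). At the higher doses in siACL the medians were negative and not called. At 2 mM 3 were higher and 6 lower (median -0.019, adjusted p = 0.373), and at 5 mM 5 and 12 (median -0.099, adjusted p = 0.0776). Hypoxia targets were not called in siMock at 5 mM (8 of 15 higher and 4 lower, the same adjusted over the list alone; median 0.084, adjusted p = 0.49), with EGLN3 at 1.29.

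Epithelial junction and keratin genes fell in siMock at 5 mM (14 of 25 lower and 4 higher, the same adjusted over the list alone; median -0.223, adjusted p = 0.0232), with CLDN1 (2.11) higher. At 0.5 mM their median was 0.089 (adjusted p = 0.0374; adjusted p = 0.0502 with an estimated correlation). Mesenchymal genes rose in siMock at 0.5 mM (5 of 13 higher and none lower, 6 and 0 adjusted over the list alone; median 0.105, adjusted p = 0.014), including SNAI2 (0.84). In siACL their median was 0.099 at 0.5 mM (adjusted p = 0.0405; adjusted p = 0.0598 with an estimated correlation) and 0.104 at 2 mM (adjusted p = 0.0246). Enterocyte genes were not called in siMock (median 0.109 at 5 mM, 6 of 19 higher and 2 lower, also adjusted over the list alone, adjusted p = 0.533), though CEACAM6 rose by 2.29. In siACL at 0.5 mM their median was 0.095 (adjusted p = 0.0388; adjusted p = 0.0517 with an estimated correlation; 0.063 without replicate 3 of siACL at 0.5 mM and 0.048 without replicate 3 of untreated siACL). Goblet and enteroendocrine genes (median -0.096, mean 0.032, at 5 mM in siMock, adjusted p = 0.803) and cancer-testis genes (median -0.009, mean 0.351, adjusted p = 0.49) were not called. Single members rose there, SYP by 3.12 and SPANXA1 by 2.37. Fibroblast markers (median 0.061, adjusted p = 0.76) and leukocyte and endothelial markers (median 0.075, adjusted p = 0.384) were not called at 5 mM in siMock, where the endothelial gene VWF rose by 1.74.

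Stress response and cholesterol synthesis genes were higher in siACL than in siMock without butyrate, with medians of 0.129 and 0.122. Untreated siMock arrays alone as the source are argued against, since both lists were also higher at 0.5 mM, in other arrays, with a larger adjusted p of 1.87e-12. An innate immune response to the siRNA cannot be told apart, since the interferon-stimulated genes had a median of 0.07 (jackknife SE 0.026), with 4 of 24 higher and none lower. With butyrate this list went both ways against siMock. At 0.5 mM, where the stress response (0.209) and cholesterol (0.183) medians were positive, its median was -0.056 (6 lower and 1 higher). It was 0.063 at 2 mM (5 higher and 2 lower) and 0.055 at 5 mM (5 higher and 1 lower). A shortage of citrate-derived acetyl-CoA in the depleted cells may be a biological explanation, and off-target effects of the siRNA may be another; the 1 knockdown in the labels leaves both untested.

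For comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 4022 and 2, 6894 and 2, and 9237 and 2 for siMock at 0.5, 2 and 5 mM. For siACL they were 1315 and 3, 4816 and 0, and 8222 and 0. For siACL against siMock they were 1147 and 12, 3213 and 1, 3479 and 2, and 2493 and 2 at 0, 0.5, 2 and 5 mM.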
